A study of Mus musculus with 24 samples.

How the data were processed

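Gene expression was measured by RNA sequencing in cells sorted from mouse brain slices. The slices had been kept for 2 days with phosphate-buffered saline (PBS) or with exosomes at 5 µg per slice, and the exosomes carried PKH67, a green fluorescent membrane dye. Endothelial cells were gated as CD45-negative and CD31-positive, and microglia as CD45-positive with low CD11b and low CD49d. The labels name 24 samples in 8 groups of 3: both cell types, each with PBS, exosomes called wild type (WT) and exosomes of 2 knockouts called KO1 and KO2. Each sample also carries a letter, A, B or C, and the labels do not say whether the letters stand for separate animals, cultures or preparations. The p-values therefore measure the spread between these samples, which may be technical. The labels describe the PBS samples, like the others, as sorted for exosome signal, so the gate applied to them is unclear.

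Reads were processed by the authors with FastQC 0.11.7, Trimmomatic 0.38, Salmon 0.10.0 and DESeq2 1.18.1 on GRCm38.p6, per the submitters' processing notes, which give no role or order. For each cell type the authors deposited a table of 20555 genes in log2 units, named in the labels as variance-stabilised counts. In those deposited log2 values a gene with no reads sits at a floor, 13.2814 in endothelial cells and 9.8893 in microglia. The endothelial table held 10 libraries (PBS A, B and C, WT A and B, KO1 A, B and C, KO2 B and C). The microglia table held 11 (PBS A and B, and all 3 letters of WT, KO1 and KO2). WT C and KO2 A of the endothelial cells and PBS C of the microglia were not analysed here, so the groups held 2 or 3 libraries where 3 had been assumed. A second pair of deposited tables lists genes from the authors' own comparison, 362 in endothelial cells and 238 in microglia. In these the authors deposited a mean normalised count as a signal, a log2 fold change, its standard error and a test statistic, which are scores, and p-values with their adjusted form. These tables are named for a likelihood ratio test, a test of any difference among the groups. Their p-values are therefore not tests of the fold change printed beside them. The highest adjusted p listed was 0.0496 in endothelial cells and 0.0498 in microglia, and the contrast behind the fold change is not given in the sources used here.

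Identifiers were matched to symbols and to positions on GRCm38.p6 in a reference gene table, where 20537 of the 20555 had a symbol. Variance-stabilised values compress differences at low counts, so a difference on the deposited log2 scale understates the change of weakly expressed genes. In the endothelial table, whose floor is high, it understates the change of strongly expressed genes such as H2-K1 and Ptgs2 as well. Normalised counts were therefore also recovered from the deposited values, as a description only. In endothelial cells the transform has a closed inverse, and the recovered mean divided by the authors' mean was 1.0000 over 362 genes. In microglia a monotone curve was fitted through the authors' 238 means, with a largest error of 0.621% for genes held out. It is not anchored below a mean of 54.3 normalised counts, and low microglia values are approximate. The recovered totals were 25.7 to 28.0 M normalised counts per endothelial library and 27.2 to 29.8 M per microglia library. Endothelial values stepped in units of 0.722 to 1.53 normalised counts, taken as 1 read, which gives 18.3 to 35.5 M reads per library. Of the values between 1 and 20 such units, 72.3 to 88.9% lay within 0.05 of a whole number. No such unit was found for microglia, so their read depth is unknown.

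Differences were tested with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a mean-variance trend and all libraries of a cell type in 1 fit. The main fit held no term for the letters, and Benjamini-Hochberg adjustment had a threshold of 0.05. The contrasts were WT minus PBS, the mean of KO1 and KO2 minus WT, each knockout minus WT, the knockout mean minus PBS, and KO1 minus KO2, besides an F test over the 4 groups. Genes entered when their mean lay at least 1 above the floor, which left 1068 of 14164 varying genes in endothelial cells and 5227 of 13950 in microglia. Because the floor of the endothelial table is high, that filter kept only strongly expressed genes there. Genes that are off in some groups were reached only without the filter.

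The 40 gene lists covered chemokines, inflammatory cytokines and prostaglandin synthesis, NF-kB targets, type I interferon response, antigen presentation, leukocyte adhesion, blood-brain barrier, angiogenesis, Wnt response, TGF-beta and BMP response, hyaluronan metabolism, extracellular matrix, hypoxia and glycolysis, cell cycle, immediate early and dissociation stress, unfolded protein response, cholesterol synthesis, lipid efflux and storage, lysosome, oxidative stress, homeostatic microglia, disease-associated microglia, alternative activation, oxidative phosphorylation, mitochondrially encoded transcripts, ribosomal proteins and p53 targets. The other 13 held markers of endothelium, microglia, border-associated macrophages, monocytes and neutrophils, lymphocytes, pericytes and smooth muscle, fibroblasts and meninges, astrocytes, oligodendrocytes, oligodendrocyte precursors, neurons, ependyma and choroid plexus, and erythrocytes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes tested, whereas fry asks whether its members move, on balance, one way.

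The groups, tests, lists, filter and rule for naming genes were set before the data were examined. The rule took up to 8 genes per direction for WT minus PBS and knockout minus WT among genes past the threshold with non-overlapping groups. Where none passed, it took the 3 of smallest p per direction. It also took called members of passing lists, up to 3 called genes per direction of the other contrasts, the 5 of smallest adjusted p in each table of the authors, Cemip, Ptgs2, Tnf, the chemokines and the sort markers. No member of a passing list was called, so the 4 of smallest p were named, an extension made after seeing the data. Some genes that the rule or a list would name are not reported here. Alternatives set beforehand were no filter, a stricter filter (3 above the floor), quantile normalisation, equal medians, the letter as a block, no variance trend, robust variance, library weights, only the groups compared, and each library left out in turn. Those added after seeing the data left out the libraries lettered C, combined that with the block or with no filter, or used log2 of the recovered counts plus 1, 10 or 50. Values were tabulated with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, and plotted with matplotlib 3.10.9.

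The tests were tried on simulated data with 200 changed genes. For WT minus PBS over the 1068 endothelial genes, 79.3% of genes changed by 0.5 log2 units and 99% of those changed by 1 were recovered. Over the 5227 microglia genes the shares for that contrast were 1.2% and 91.4%. For knockout minus WT they were 84.6% and 99.5% in endothelial cells, and 42.6% and 96.5% in microglia. The simulated values had each gene's spread as estimated by the limma fit and no structure by letter, and the changed genes were drawn at random. The shares need not hold for genes with a far larger spread, such as Ptgs2 and Ccl5 in microglia. The deposited scales also differ, so a shift of 0.5 or 1 is not the same change of counts in both cell types. A microglia difference of 0.5 was thus mostly not detectable, and false calls stayed between 3.1 and 5.8% except at 14.3% for the 0.5 shift of WT minus PBS in microglia.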

Results

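Slices of mouse brain were exposed for 2 days to exosomes, small membrane vesicles that cells release, or to PBS, and endothelial cells and microglia were then sorted and sequenced. The labels call all samples sorted for the signal of the dyed vesicles, although PBS slices received none. The series title concerns CEMIP, a protein that binds and helps break down hyaluronan, carried by tumour exosomes and linked to brain metastasis. The design therefore asks 2 questions of each cell type: what exosomes of unmodified (WT) donor cells change against PBS, and whether exosomes of the knockouts KO1 and KO2 differ from WT. Endothelial cells, which line blood vessels, were measured in 10 libraries (3 PBS, 2 WT, 3 KO1 and 2 KO2). Microglia, the resident macrophages of the brain, were measured in 11 (2 PBS and 3 each of WT, KO1 and KO2). In endothelial cells 11305 to 11952 genes lay above the floor in the PBS libraries and 9235 to 10739 in the exosome libraries other than KO1 B (11531), although PBS A and PBS B had the fewest estimated reads (18.3 and 18.8 M, against 29.3 M in PBS C and 25.8 to 35.5 M with exosomes). Microglia libraries held between 10139 and 11292 genes above the floor. The 10 most abundant genes held 6.6 to 8.7% of the normalised counts in endothelial libraries and 16.4 to 21.3% in microglia. Levels below are recovered normalised counts, with the SD between libraries, and differences are on the deposited log2 scale with the standard error (SE) of the limma fit. Endothelial differences on that scale are smaller than the log2 ratios of the counts, also for strongly expressed genes.

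The knockouts were made in the donors of the exosomes and not in the mouse, so mouse Cemip (gene 80982; chromosome 7, 83932857 to 84086693, GRCm38.p6) does not check the labels. Its transcript lay between 0 and 66.2 normalised counts in the endothelial libraries and between 0 and 4.30 in microglia. The sort markers followed the gates. Pecam1, which encodes CD31, stood at 44780 ± 3472 (SD, n = 3) in PBS endothelial cells and at 0 to 283 per library in microglia. Ptprc, which encodes CD45, was listed at 0 in all endothelial libraries except KO1 B (119) and KO2 C (290), and ranged from 1530 to 3980 in microglia. Itgam (CD11b) averaged 1624 ± 360 (SD, n = 2) in PBS microglia. In endothelial cells Itgam stood at 27.3 or less except in WT B (1226), KO1 B (1298) and KO2 B (438). Itga4 (CD49d) was low in both types, at 16.2 to 401 in endothelial cells and 18.6 to 102 in microglia. Tnf, a proinflammatory cytokine, reached at most 874 in endothelial cells.

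Markers of each cell type were summed per library. Endothelial markers summed to 296081 to 376788 normalised counts in endothelial libraries and to 545 to 1292 in microglia, and microglia markers to 58575 to 97268 in microglia. In endothelial libraries the microglia markers summed to 5069 in WT B, 3606 in KO1 B and 4759 in KO2 B, against 113 to 1782 in the others. Pericyte and smooth muscle markers were likewise high in those 3 libraries (8467, 7473 and 6349) and lay between 687 and 4595 elsewhere. Choroid plexus and ependyma markers moved with treatment and letter: they summed to 95 to 4613 in PBS endothelial libraries. They summed to 168528 to 283034 in the 5 exosome endothelial libraries lettered A or B, to 2938 in KO1 C and to 17538 in KO2 C. In microglia these markers summed to 1 to 10334. Fibroblast and meninges markers in endothelial libraries summed to 593 to 1501 with PBS, 1859 and 4519 in WT A and B, 6259 and 7727 in KO1 A and B, 5720 in KO2 B, and 166 and 1782 in KO1 C and KO2 C. Endothelial libraries also held markers of astrocytes (8690 to 41086), border-associated macrophages (8049 to 19129) and oligodendrocytes (376 to 2854). Few members carried these sums, so they do not show how many such cells were present. Per endothelial library, 1 to 4 of 12 astrocyte, 1 to 4 of 10 border-associated macrophage and 1 to 2 of 11 oligodendrocyte markers reached 100 counts. Markers of monocytes and neutrophils (160 to 573), lymphocytes (5 to 82), neurons (8 to 698), oligodendrocyte precursors (0 to 669) and erythrocytes (0 to 608) were scarce there. Microglia libraries held oligodendrocyte (3197 to 9182), border-associated macrophage (2489 to 9378) and astrocyte markers (524 to 2700). Their monocyte and neutrophil (230 to 937), pericyte (0 to 801), neuron (9 to 367), oligodendrocyte precursor (0 to 304), erythrocyte (0 to 294), fibroblast (0 to 181) and lymphocyte (0 to 173) markers were scarce.

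Endothelial cells given WT exosomes held more transcripts of the type I interferon response and of antigen presentation than PBS cells. All 5 tested interferon genes were higher, with a median log2 difference of 0.93 (adjusted p = 0.00153, limma camera). Irf7, a transcription factor that amplifies interferon signalling (gene 54123; chromosome 7, 141263183 to 141266499), averaged 1640 ± 706 (SD, n = 3) with PBS and 22400 ± 13880 (SD, n = 2) with WT exosomes. Ifitm3, which restricts virus entry, averaged 39570 ± 13520 and 138000 ± 54150, with log2 differences of 1.43 (SE 0.426) for Ifitm3 and 1.37 (SE 0.383) for Irf7. Ifit3 and Rtp4 differed by 0.93 and 0.64. All 5 antigen presentation genes were higher, by a median of 0.73 (adjusted p = 0.00153). They included the class I heavy chain H2-K1, at 7214 ± 2833 (SD, n = 3) and 21780 ± 4407 (SD, n = 2), its partner chain B2m (1.13), and Tap2 (0.36) and Tapbp (0.36), which load peptides. Adjusted over the list alone, 2 interferon and 3 antigen presentation genes passed, and both lists had an adjusted p = 0.419 with an estimated correlation. Neither call ended when any single library was left out. Beside both stand the summed choroid plexus markers in WT A and WT B (188000 and 171684, against 95 to 4613 with PBS), the fibroblast and meninges markers there (1859 and 4519, against 593 to 1501) and the microglia markers in WT B (5069, against 784 to 1065).

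Inflammatory mediators were higher in the same comparison and targets of TGF-beta and BMP signalling were lower. All 6 tested cytokine and prostaglandin genes lay above PBS (median 0.26, adjusted p = 0.00947, limma camera). Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis (gene 19225; chromosome 1, 150100031 to 150108234), averaged 20990 ± 3280 (SD, n = 3) with PBS and 59180 ± 12130 (SD, n = 2) with WT exosomes, a log2 difference of 1.02 (SE 0.244). Csf3, the granulocyte growth factor, differed by 1.01, Il6 by 0.29 and Tgfb1, which mainly restrains immune cells, by 0.24. All 6 TGF-beta and BMP genes lay below PBS, by a median of -0.28 (adjusted p = 0.00626). Ccn1, a matrix-associated protein, averaged 21590 ± 13940 (SD, n = 3) with PBS and 5899 ± 654 (SD, n = 2) with WT exosomes (-0.80). The endothelial BMP receptor Acvrl1 differed by -0.38, the BMP target Id1 by -0.30 and the receptor Tgfbr2 by -0.26. Adjusted over the list alone, 1 cytokine gene and 3 TGF-beta genes passed, and both lists had an adjusted p = 0.419 with an estimated correlation. Both calls ended without WT B (0.095 for cytokines, 0.0971 for TGF-beta and BMP), where Il6 turned to -0.30, and the TGF-beta and BMP call also without the filter (0.155) and on log2 of recovered counts (0.08 to 0.134). WT B also held the highest sums of microglia and of pericyte and smooth muscle markers (5069 and 8467), and choroid plexus markers stood at 188000 in WT A and 171684 in WT B, against 4613 or less with PBS. Fibroblast and meninges markers stood at 1859 and 4519 there, against 1501 or less.

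The disease-associated microglia list also passed in endothelial cells (5 of 6 higher, median 0.39, adjusted p = 0.0137, limma camera). Its members there are general genes: Fth1, the iron-storing ferritin heavy chain, differed by 0.59, Apoe, a lipid carrier, by 0.59, Cd63, a protein of late endosomes and exosomes, by 0.41, and Ctsd, a lysosomal protease, by 0.37. Beside it stand the microglia markers in WT B (5069), and in WT A and WT B the choroid plexus (188000 and 171684) and fibroblast and meninges markers (1859 and 4519). Ribosomal protein genes were higher by a small margin, 13 of 16 with a median of 0.07 (camera adjusted p = 0.0173, and 0.0831 with the letter as a block). Rpl19 differed by 0.20, Rpl7 by 0.18 and Rps29 by 0.17. Adjusted over the list alone, no gene of either list passed, and both had an adjusted p = 0.419 with an estimated correlation. Without WT B they had 0.198 and 0.0971, the disease-associated microglia list had 0.206 without the filter and 0.0667 on log2 of recovered counts plus 50, and ribosomal proteins had 0.0705 without PBS C and 0.091 with the C libraries left out.

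Gene by gene, 0 of 1068 endothelial genes passed for WT minus PBS with limma, against 187 at an unadjusted p under 0.05. The letter as a block raised that count, as given with the alternatives below. More genes lay above the floor in each PBS library (11305 or more) than in WT A and WT B (9235 and 10607). The genes of smallest p, none of which passed (adjusted p = 0.115), were Pabpc1, a poly(A)-binding protein (0.45, SE 0.0831), H2-K1 (0.80, SE 0.178) and Gorasp2, a Golgi stacking protein (0.32, SE 0.076) among those higher. Among those lower they were Plat, tissue plasminogen activator (-0.77, SE 0.152), Ppp1r2, a phosphatase inhibitor (-0.51, SE 0.102), and Nedd9, a scaffold of cell migration (-0.60, SE 0.123). Plat averaged 58430 ± 3291 (SD, n = 3) with PBS and 27360 ± 160 (SD, n = 2) with WT exosomes. The count of 0 became 14 without PBS B, 5 without KO1 C, 2 without WT B and 14 (10 higher, 4 lower) with only the WT and PBS libraries in the fit. The 14 without PBS B included lower values of the heat shock genes Hspa1a (-1.96) and Hspa1b (-2.09), which in PBS B stood below the other PBS libraries (Hspa1b 16780, against 152500 in PBS A and 72140 in PBS C). Genes outside the naming rule are named here after their values were seen. With the C libraries left out, a choice made after seeing the data, 1 gene passed, Ttr, the choroid plexus transthyretin (3.59, adjusted p = 0.00078), with 140 at an unadjusted p under 0.05.

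The other endothelial lists did not pass for WT minus PBS in limma's camera. Angiogenesis genes were mostly lower (13 of 16, adjusted p = 0.0542), among them the VEGF receptor gene Kdr (-0.63), and hypoxia and glycolysis genes mostly higher (7 of 9, adjusted p = 0.0542). All 9 tested blood-brain barrier genes lay below PBS, by a median of -0.12 (adjusted p = 0.126). They included Slc2a1, the glucose transporter of brain vessels (-0.51), and Cldn5, the main tight junction claudin (-0.11). Chemokines were split (3 higher, 2 lower, adjusted p = 0.229): the neutrophil attractants Cxcl1 (0.66) and Cxcl2 (0.77) and the monocyte attractant Ccl2 (0.45) lay above PBS, and Cxcl12 (-0.74) and Cx3cl1 (-0.14) below. NF-kB targets had 6 of 8 members higher (adjusted p = 0.166), p53 targets 5 of 6 lower (0.197) and lysosomal genes 7 of 10 higher (0.229). Oxidative stress (0.453), immediate early and dissociation stress (0.547), unfolded protein response, extracellular matrix and oxidative phosphorylation (each 0.644), endothelium markers (0.647) and leukocyte adhesion (0.836) moved both ways. Too few members of the remaining lists passed the filter, so they were tested only without it, where Wnt response genes were lower (15 of 18, adjusted p = 0.0411) and alternative activation (0.506), cholesterol synthesis (0.867), cell cycle and homeostatic microglia (each 0.986), hyaluronan metabolism and lipid efflux (each 0.988) did not pass. The unfiltered interferon list held 28 members, 25 of them higher (adjusted p = 4.76e-12). Choroid plexus markers (adjusted p = 0.00591) and microglia markers (adjusted p = 0.0026) were higher there too. Mitochondrially encoded transcripts were not among the genes tested. The unfiltered lists were not tested with an estimated correlation.

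**Figure D1:**
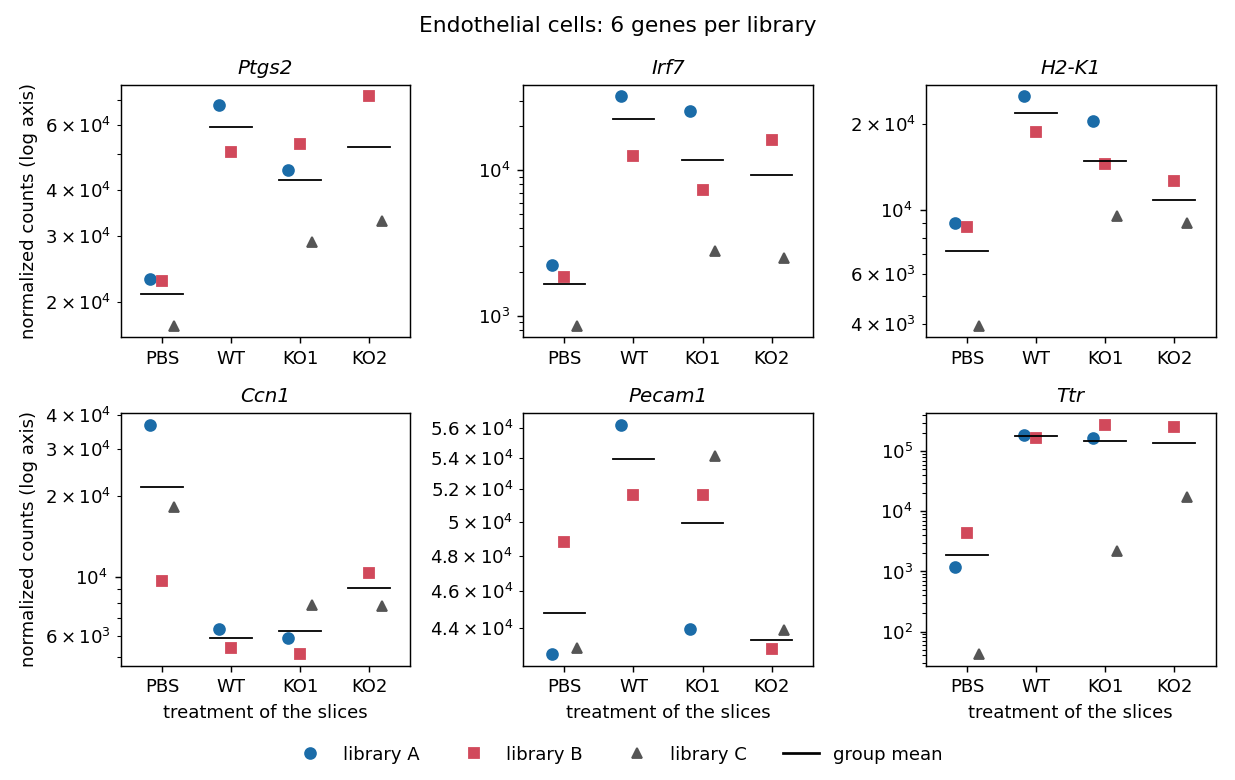
Recovered normalised counts (log axis) of 6 genes in endothelial cells by group, where each point is 1 library, its colour and marker give the letter, and the black line is the group mean. Ptgs2 lay between 17210 and 23010 in the PBS libraries and between 28970 and 71480 in the exosome libraries, and Ttr was at 164800 or more in the exosome libraries lettered A or B and at most 17390 in those lettered C.

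Antigen presentation was the list that passed between knockout and WT exosomes in endothelial cells. All 5 antigen presentation genes were lower on average with knockout exosomes, by a median of -0.43 (adjusted p = 0.02, limma camera). H2-K1 averaged 14790 ± 5415 (SD, n = 3) with KO1 and 10800 ± 2583 (SD, n = 2) with KO2, against 21780 ± 4407 (SD, n = 2) with WT. B2m differed by -0.61, Tapbp by -0.21 and Tap2 by -0.21, and without WT A these were -0.09 for B2m, -0.003 for Tapbp and 0.03 for Tap2. In letter B, the letter that held both WT and KO2, the ratio of KO2 to WT counts was 1.35 for B2m, 1.17 for Tapbp, 1 for Tap2 and 0.677 for H2-K1. The ratio of KO1 to WT lay below 1 for these 4 genes in letters A and B (0.627 to 0.93). No member passed when adjusted over the list alone, and the list had an adjusted p = 0.802 with an estimated correlation and 0.751 with the C libraries left out. The call also ended without WT A (0.396), KO1 B (0.0607), KO1 C (0.112) or KO2 C (0.45), without the filter (0.0531) and on log2 of recovered counts (0.0556 to 0.0665). With the letter as a block the antigen presentation call ended as well (camera adjusted p = 0.237). All 5 interferon genes were lower too (median -0.45, adjusted p = 0.0515). In letter B all 5 were instead higher with KO2 (median ratio of counts 1.28), while KO1 was lower in 4 of 5 there (0.747) and in letter A (0.874). Irf7 averaged 11840 ± 11960 (SD, n = 3) with KO1 and 9267 ± 9602 (SD, n = 2) with KO2. The C libraries set much of that spread, since Irf7 stood at 2801 in KO1 C and 2477 in KO2 C and between 7320 and 25400 in KO1 A, KO1 B and KO2 B, and no WT C library was analysed here.

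Ptgs2 was not resolved between knockout and WT exosomes in endothelial cells, with a log2 difference of -0.28 and a 95% interval of -0.78 to 0.22. It averaged 42510 ± 12400 (SD, n = 3) with KO1 and 52280 ± 27160 (SD, n = 2) with KO2, and its difference turned to 0.015 with the C libraries left out. With limma 0 of 1068 genes passed for knockout minus WT, against 57 at an unadjusted p under 0.05 (lowest adjusted p = 0.536). Those of smallest p that were higher were Myo1d, an unconventional myosin (0.60, SE 0.121), the semaphorin Sema6d (0.37, SE 0.0879) and Abcb1a, the P-glycoprotein drug pump of the blood-brain barrier (0.34, SE 0.0894). Abcb1a averaged 4910 ± 225 (SD, n = 2) with WT, 10180 ± 654 (SD, n = 3) with KO1 and 8264 ± 2842 (SD, n = 2) with KO2, and 5659 ± 658 (SD, n = 3) with PBS. Lower were Ogt, which attaches N-acetylglucosamine to proteins (-0.36, SE 0.0838), Gorasp2 (-0.27, SE 0.07) and Slc12a2, a chloride cotransporter (-0.48, SE 0.13). Without WT B, 3 genes passed: Myo1d (0.83), Erbin (0.87) and Map3k3 (0.63). The other tested lists had adjusted p-values of 0.145 (NF-kB targets, 7 of 8 lower) to 0.986. Among them were angiogenesis, 13 of 16 higher (0.176), cytokines, 5 of 6 lower, and chemokines, 4 of 5 lower (each 0.189), and TGF-beta and BMP, 5 of 6 higher (0.268).

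Each knockout was also set against WT. With limma 0 endothelial genes passed for KO1 minus WT (47 at an unadjusted p under 0.05, lowest adjusted p = 0.391) and 0 for KO2 minus WT (56, lowest adjusted p = 0.13). Without WT B, 2 genes passed for KO1 minus WT, Erbin and Myo1d. The knockouts differed from each other in 1 gene, Tgm2, the tissue transglutaminase that crosslinks proteins (gene 21817; chromosome 2, 158116405 to 158146392). It was lower with KO1, at 7673 ± 891 (SD, n = 3), than with KO2, at 24850 ± 5238 (SD, n = 2), by -0.86 (SE 0.117, adjusted p = 0.019), with 42 genes at an unadjusted p under 0.05. PBS and WT cells held 12150 ± 2737 and 9125 ± 1165 of Tgm2. The call ended without KO1 A (adjusted p = 0.0798), KO1 B (0.0736), KO1 C (0.0932) or KO2 B (0.413), and held without KO2 C (0.041). It also ended without the filter, with the C libraries left out, with only the knockout libraries in the fit and on log2 of the recovered counts.

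Of the 6 endothelial lists that passed for WT minus PBS, 5 also passed in the same direction for the mean of both knockouts minus PBS, and ribosomal proteins did not (adjusted p = 0.0532). TGF-beta and BMP genes were lower (6 of 6, median -0.19, adjusted p = 0.0247, limma camera), with Ccn1 at -0.67, Id3, a BMP target, at -0.29, Id1 at -0.24 and Acvrl1 at -0.15. Interferon (5 of 5 higher, median 0.58, adjusted p = 0.0302) and antigen presentation (5 of 5, median 0.24, 0.0388) genes were higher, with Irf7 at 0.72, Ifitm3 at 0.72, Ifit3 at 0.58, B2m at 0.52 and H2-K1 at 0.37. Cytokine and prostaglandin genes were higher as well (5 of 6, median 0.22, 0.0388), with Ptgs2 at 0.74 (SE 0.197), and so was the disease-associated microglia list (5 of 6, 0.0247), with Apoe at 0.49, Ctsd at 0.40, Fth1 at 0.34 and Cd63 at 0.28. Beside these stand the summed microglia markers in KO1 B and KO2 B (3606 and 4759), and in KO1 A, KO1 B and KO2 B the choroid plexus markers (168528 or more) and the fibroblast and meninges markers (6259, 7727 and 5720). Adjusted over the list alone, 3 TGF-beta genes, 1 cytokine gene and none of the others passed, and all 5 lists had an adjusted p = 0.587 with an estimated correlation. All 5 calls ended without KO2 B (0.113 for TGF-beta and BMP, 0.183 for disease-associated microglia, 0.273 for the others), and TGF-beta and BMP had 0.0729 with the C libraries left out, 0.0527 without the filter and 0.0513 on log2 of recovered counts plus 1. Antigen presentation, cytokines and interferon ended without PBS C (0.221, 0.0726 and 0.0704) or KO1 A (0.0923, 0.088 and 0.088), and cytokines without KO1 B (0.0809). With limma 0 genes passed, against 148 at an unadjusted p under 0.05 (lowest adjusted p = 0.198). The letter as a block raised that count too. Without PBS B or without KO1 C 7 passed, and 4 with the C libraries left out, Ttr (3.95), Enpp2 (2.09), the matrix protease Mmp3 (1.74) and Lgals3bp (0.86), with 133 at an unadjusted p under 0.05. Enpp2, like Ttr, is abundant in choroid plexus.

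The endothelial responses to WT and to knockout exosomes resembled each other across genes. The correlation of both differences from PBS was 0.864 over 1068 genes, which are not independent replicates, and 77.1% of genes had the same sign. Because the PBS libraries enter both differences, unchanged groups gave a mean correlation of 0.501 (range 0.353 to 0.649 in 100 simulations) and 66.8% of the same sign. The covariance was 0.0545, against 0.0118 simulated. The 3 PBS libraries could not be divided into 2 sets of at least 2, so part of the excess in the correlation may come from the shared controls. The simulated groups held no structure by letter, so letters shared by WT and knockout libraries may account for part of it too. Choroid plexus markers were high in the WT and knockout libraries lettered A or B (168528 to 283034, against 95 to 4613 with PBS). What such transcripts add to the correlation was not tested.

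Microglia given WT exosomes held more transcripts of interferon, NF-kB and chemokine genes than PBS microglia in the libraries lettered A and B, and not in WT C. No PBS C microglia library was analysed here, so WT C was set against PBS A and B only. A missing response in letter C cannot be told apart from a lower baseline of that letter. All 21 tested interferon genes were higher on average, by a median of 0.88 (adjusted p = 2.78e-07, limma camera). Zbp1, a sensor of nucleic acids, averaged 364 ± 8.21 (SD, n = 2) with PBS and 2724 ± 2174 (SD, n = 3) with WT exosomes, a log2 difference of 0.91. Bst2, which tethers virus particles (1.00), Usp18, which limits interferon signalling (1.15), and Parp14, an ADP-ribosyltransferase (0.65), lay above PBS as well. Of 14 NF-kB targets 13 were higher (median 0.40, adjusted p = 0.000845), among them Tnfaip3 (0.82), which feeds back on NF-kB, Sod2 (0.89), the mitochondrial superoxide dismutase, Tnfaip2 (0.65) and the apoptosis regulator Cflar (0.44). Chemokines followed, with 11 of 14 higher (median 0.51, adjusted p = 0.0288). Cxcl2 averaged 26720 ± 14260 (SD, n = 2) with PBS and 100900 ± 64040 (SD, n = 3) with WT exosomes, and Cxcl1, Cxcl10, an attractant of T cells, and Ccl2 differed by 1.33, 1.28 and 1.13. Below PBS were Ccl6 (-0.84), Ccl9 (-0.18) and Pf4 (-0.07). No member of the 3 lists passed when adjusted over the list alone, and all 3 had an adjusted p = 0.814 with an estimated correlation. The interferon call held without each library in turn, and the NF-kB call ended without WT B (0.0813). The chemokine call ended without PBS A (0.129), PBS B (0.215), WT A (0.119), WT B (0.498) or KO2 A (0.0632), without the filter (0.108) and on log2 of recovered counts (0.121 to 0.186). Beside these lists stand the border-associated macrophage markers in WT B (9103, against 4807 and 2767 with PBS, 4665 in WT A and 3259 in WT C) and the monocyte and neutrophil markers there (937, against 267 and 230 with PBS, 284 in WT A and 369 in WT C). Microglia markers summed to 58575 in WT C, against 78098 and 96580 with PBS, 97268 in WT A and 81465 in WT B.

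Library by library, Ptgs2 in microglia stood at 10287 and 9158 normalised counts with PBS, and at 28373, 47548 and 4293 in WT A, B and C. Tnf (gene 21926; chromosome 17, 35199367 to 35202007) stood at 3598 and 4809 with PBS and at 13371, 13484 and 4621 with WT. Ccl5, a T cell and monocyte attractant (gene 20304; chromosome 11, 83525778 to 83530518), stood at 10763 and 8211 with PBS and at 138500, 51570 and 6027 with WT. The log2 differences were 0.96 for Ptgs2 (SE 0.906, 95% interval -1 to 2.93), 0.98 for Tnf (SE 0.375) and 2.04 for Ccl5 (SE 1.52), and none passed. The letter as a block raised the count of genes passing for WT minus PBS, as given with the alternatives below. Without it, limma passed 0 of 5227 microglia genes for that contrast, against 253 at an unadjusted p under 0.05 (lowest adjusted p = 0.615). Those of smallest p that were higher were Fam234a (0.97, SE 0.176), the kinase Map3k2 (0.97, SE 0.191) and Sart3, a splicing factor (0.55, SE 0.136). Fam234a stood at 0 and 156 in the PBS libraries and at 1040 to 2110 in the exosome libraries. Lower were Aldh18a1, of proline synthesis (-0.68, SE 0.175), Hk1, a hexokinase (-0.63, SE 0.162), and Plxdc2 (-0.65, SE 0.175).

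With the C libraries left out, 8 microglia genes passed for WT minus PBS, with 356 at an unadjusted p under 0.05, and all 8 were higher. They were Cxcl1 (2.02), Acod1, which makes the antimicrobial metabolite itaconate (2.79), Ccl2 (1.65), Sod2 (1.46), Ptgs2 (1.92, SE 0.253), Tnf (1.41, SE 0.186), Cxcl2 (2.78) and the membrane protease Mmp14 (1.04). Their limma adjusted p-values ran from 0.00457 for Cxcl1 and Acod1 to 0.0483 for Mmp14, with 0.0152 for Ptgs2 and Tnf. The C libraries were left out after they were seen to lie near PBS for such genes, so these calls are not independent evidence of the difference.

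**Figure D2:**
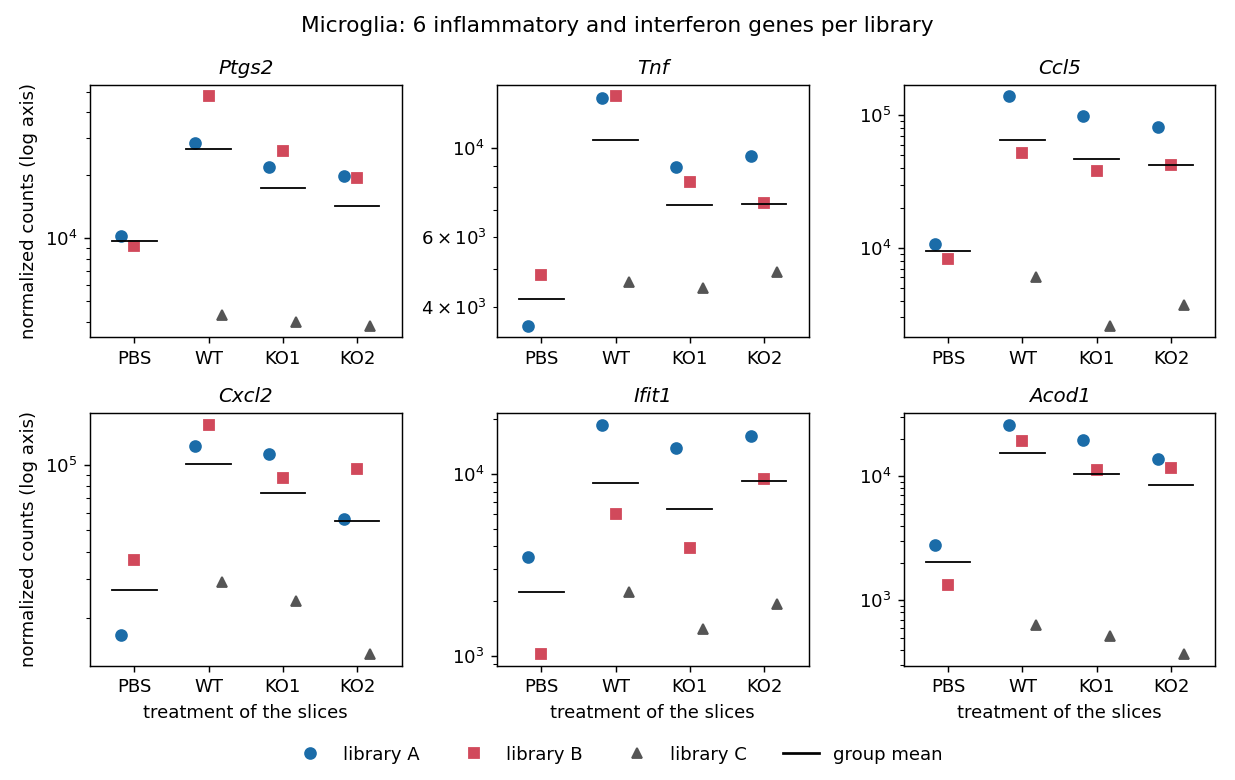
Recovered normalised counts (log axis) of 6 genes in microglia by group, where each point is 1 library, its colour and marker give the letter, and the black line is the group mean. For Ptgs2 the exosome libraries lettered A or B lay between 19353 and 47548 and those lettered C between 3824 and 4293, below the PBS libraries at 9158 and 10287.

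Other microglia lists did not pass for WT minus PBS. Cytokine and prostaglandin genes had 7 of 11 members higher (median 0.58, adjusted p = 0.401, limma camera), among them Ptges (1.184), which completes prostaglandin E synthesis, Il1rn (0.92) and Il1b (0.64), and the constitutive Ptgs1 lower (-0.32). Antigen presentation had 10 of 14 higher and ribosomal proteins 25 of 30 lower (each 0.076). Disease-associated microglia genes were mostly lower (12 of 19, 0.255), with Spp1, osteopontin, at -2.16 and Ctsd at -0.64. Lysosomal genes (16 of 25 lower) had an adjusted p of 0.339 and oxidative phosphorylation (16 of 24 lower) of 0.382. Homeostatic microglia, hypoxia and glycolysis, and immediate early and dissociation stress each had 0.4, and cholesterol synthesis 0.625. Leukocyte adhesion, extracellular matrix, oxidative stress, lipid efflux and microglia markers each had 0.664, TGF-beta and BMP 0.68, unfolded protein response 0.687 and blood-brain barrier 0.695. Hyaluronan metabolism, the process CEMIP acts in, had 4 of 6 members lower and p53 targets likewise had 0.889. Tested only without the filter, cell cycle (0.719), angiogenesis (0.762), Wnt response (0.876) and alternative activation (0.911) did not pass. The sort marker Ptprc differed by 0.46 and Itgam by 0.03 in microglia, and neither passed. Itgam turned to -0.19 without WT B, -0.07 without PBS B and -0.06 without WT A.

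Knockout and WT exosomes were not told apart in microglia by the fit without the letters. Ptgs2 averaged 26740 ± 21670 (SD, n = 3) with WT, 17290 ± 11690 (SD, n = 3) with KO1 and 14330 ± 9101 (SD, n = 3) with KO2, a log2 difference of -0.57 with a 95% interval of -2.09 to 0.95. Tnf averaged 10490 ± 5085 with WT, 7223 ± 2408 with KO1 and 7264 ± 2343 with KO2, a difference of -0.40 with an interval of -1.03 to 0.23. Both intervals include the gap between the C libraries and the others, which WT and both knockouts share. They are therefore not a measure of the difference within letters. The Ptgs2 values of the KO1 libraries A, B and C were 21952, 25939 and 3990, those of KO2 19812, 19353 and 3824. Ccl5 stood at 98276, 38255 and 2597 with KO1 and at 81230, 41816 and 3707 with KO2. Of the interferon genes 18 of 21 were lower than with WT, of the NF-kB targets 11 of 14, of the chemokines 9 of 14 and of the cytokine genes 7 of 11. No list passed (lowest adjusted p = 0.637, limma camera). Single libraries decided the sign for several genes: Ptgs2 turned to 0.11 and Ccl2 to 0.055 without WT B, and Acod1, Ccl5, Ccl2 and Ifit1 turned to 0.17, 0.45, 0.11 and 0.49 without WT A. Leaving out 1 library also leaves the letters unbalanced. Within letters, all 6 ratios of a knockout to WT counts lay below 1 for Acod1 (0.526 to 0.819), Ccl5 (0.431 to 0.811) and Ptgs2 (0.407 to 0.93), and 5 of 6 for Ccl2 (above 1 for KO2 in letter C) and Ifit1 (1.57 for KO2 in letter B). The KO1 and KO2 ratios of a letter share the same WT library, so they are not independent. In letter B, KO2 was above WT in 16 of 21 interferon genes. Without KO1 C, Ccl5, Ccl2 and Ifit1 turned to 0.08, 0.06 and 0.10, and without KO2 C to 0.01, 0.01 and 0.17.

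With limma 0 microglia genes passed for knockout minus WT (132 at an unadjusted p under 0.05, lowest adjusted p = 0.999), for KO1 minus WT (145, 1) and for KO2 minus WT (118, 1), and 0 for KO1 minus KO2 (143, 0.999). Leaving out the C libraries kept the count for knockout minus WT at 0, with 160 at an unadjusted p under 0.05. The genes of smallest p that were higher with knockout exosomes were the histone deacetylase Hdac2 (0.50, SE 0.122), the p53 inhibitor Mdm4 (0.50, SE 0.135) and Smg1, a kinase of RNA surveillance (0.55, SE 0.162). Those lower were Ap3d1, of an adaptor complex for vesicle traffic (-0.55, SE 0.142), Me1, malic enzyme (-0.41, SE 0.117), and the deubiquitinase Usp4 (-0.50, SE 0.149).

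Against PBS, knockout exosomes also went with higher interferon and NF-kB transcripts in microglia, in the libraries lettered A and B and not in KO1 C or KO2 C. Those C libraries too were set against PBS A and B only, so a lower baseline of letter C cannot be told apart. The interferon list mean of KO1 A, B and C lay at 1.66, 0.39 and -0.17 from the PBS mean and that of KO2 at 1.501, 1.04 and -0.13, and the NF-kB list mean at -0.05 in KO1 C and -0.11 in KO2 C. All 21 interferon genes were higher on average (median 0.74, adjusted p = 8.6e-07, limma camera), with Usp18 at 0.94, Rtp4 at 0.83, Zbp1 at 0.74 and Irf9 at 0.47. NF-kB targets were higher in 13 of 14 (median 0.23, 0.0183), with Tnfaip3 and Cflar each at 0.55, Tnfaip2 at 0.32 and the adhesion molecule Icam1 at 0.31. Immediate early and dissociation stress genes were lower in 17 of 22 (median -0.18, 0.0355), with the chaperones Hspa1b at -0.81 and Hsph1 at -0.42, the transcription factor Klf2 at -0.51 and the growth inhibitor Btg2 at -0.46. That list had a camera adjusted p of 0.523 with the C libraries left out and of 0.417 with the letter as a block. Adjusted over the list alone, no gene of the 3 lists passed, and all 3 had an adjusted p = 0.985 with an estimated correlation. The interferon call held without each library in turn. The NF-kB call ended without PBS A (0.226), PBS B (0.251), KO1 B (0.144), KO2 A (0.0738) or KO2 B (0.0549). The stress call ended without PBS B (0.653), KO1 A (0.0744), KO1 C (0.165), KO2 A (0.0909) or KO2 C (0.121), with quantile normalisation (0.0593), library weights (0.0965) and the stricter filter (0.239). Beside these lists stand the border-associated macrophage markers in KO1 B and KO2 B (9378 and 7753, against 4807 and 2767 with PBS), the monocyte and neutrophil markers in KO1 A and KO2 A (565 and 549, against 267 and 230) and the microglia markers in KO1 C and KO2 C (60331 and 75182, against 78098 and 96580). With limma 0 genes passed (253 at an unadjusted p under 0.05, lowest adjusted p = 0.125). More passed with the letter as a block, as given with the alternatives below. Without PBS A 1 gene passed, Fam234a, and without PBS B 2, Crebzf and Rpl26. With the C libraries left out 3 passed, Cxcl1 (1.68), Ccl2 (1.38) and Acod1 (2.09), each with an adjusted p of 0.0114, and 364 had an unadjusted p under 0.05. The correlation across genes of the WT and knockout differences from PBS was 0.804, against 0.673 in 100 simulations of unchanged groups (range 0.621 to 0.716), and genes are not independent replicates. The covariance was 0.036 against 0.0307 simulated, and the 2 PBS libraries could not be split. These simulations too held no structure by letter, so shared letters may account for part of the excess.

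**Figure D3:**
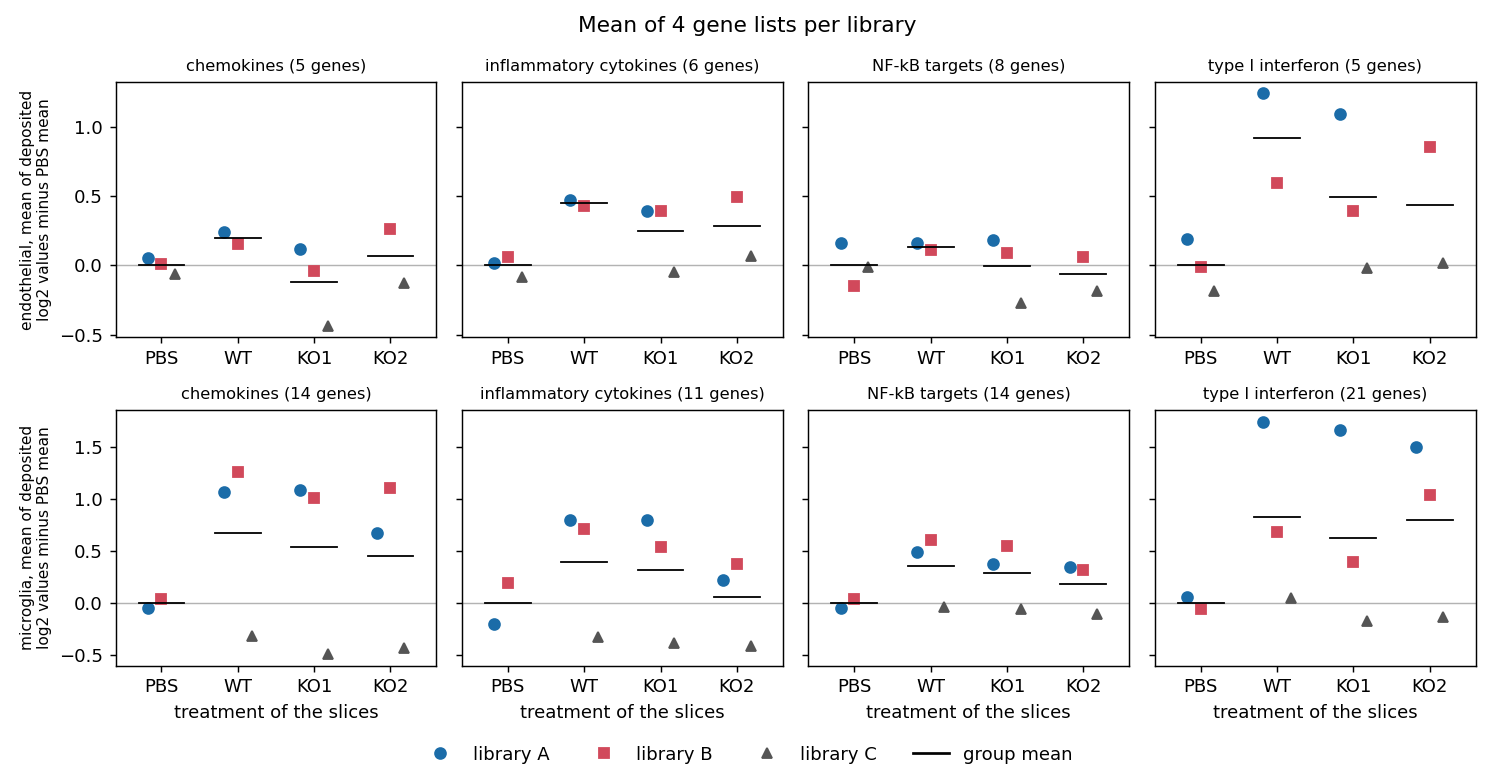
Mean deposited log2 value of 4 gene lists (chemokines, inflammatory cytokines and prostaglandin synthesis, NF-kB targets, type I interferon response) minus the mean of the PBS libraries, by cell type and group, where each point is 1 library, its colour and marker give the letter, and the black line is the group mean. In microglia the interferon list of WT A, B and C lay at 1.74, 0.68 and 0.05 from the PBS mean, and the chemokine list at 1.07, 1.26 and -0.31.

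The authors' deposited tables list 362 genes in endothelial cells (234 with a fold change above 0, 128 below) and 238 in microglia (97 above, 141 below). Across the listed genes, which are not independent replicates, the fold change of the authors' deposited table correlated with KO2 minus WT at 0.993 in endothelial cells and 0.945 in microglia. The adjusted p-values listed beside it belong to the likelihood ratio test over the groups. They do not test that fold change, nor knockout against WT. In microglia their table included 14 interferon genes, 7 chemokines, and 4 members each of the cytokine, NF-kB and antigen presentation lists. The 5 of smallest adjusted p in the authors' deposited table were Acod1 (log2 fold change -0.80, adjusted p = 2.16e-49), Ccl5 (-0.61, 9.16e-32), Ifit1, an interferon-induced RNA-binding protein (0.10, 2.29e-21), Ccl2 (-0.16, 7.65e-19) and Cxcl2 (-0.96, 4.89e-18). It also listed Ptgs2 (-0.68, 1.02e-10) and Tnf (-0.43, 5e-07). In endothelial cells the authors' deposited table held 7 interferon, 5 extracellular matrix and 4 blood-brain barrier genes, and Ptgs2 (0.09, adjusted p = 4.34e-07).

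The endothelial genes of smallest adjusted p in the authors' deposited table were mostly genes listed at 0 in both WT libraries. They were the zinc finger gene Zfp46 (adjusted p = 1.05e-41), the kinase Map4k2 (3.57e-34), Synm, an intermediate filament protein (1.07e-19), Fxyd6, a regulator of the sodium pump (5.15e-18), and Efr3b (7.83e-14). Zfp46 stood at 894, 1126 and 1190 with PBS, 1304, 1179 and 1787 with KO1 and 2740 and 2415 with KO2. Map4k2 stood at 3113, 2143 and 2294 with PBS. Synm was the exception, at 1518 ± 807 (SD, n = 2) with WT and 3405 ± 2187 (SD, n = 2) with KO2. The limma F test over the 4 groups, fitted without the letters, passed 0 genes in endothelial cells (119 at an unadjusted p under 0.05) and 0 in microglia (154), so 0 were shared with the listed genes. Without KO1 C the endothelial F test passed 2 genes, both listed. Of the listed genes that entered the test, 70 of 90 in endothelial cells and 70 of 181 in microglia had an unadjusted p under 0.05.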

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

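The comparison of directions between the cell types was run after the results were seen, and none of the differences between cell types below was tested. The deposited log2 scales of the cell types differ, so the directions can be set side by side but not the sizes. Of 114 comparisons of a gene or list, those given here had every library of the exosome group named with them (WT, or both knockouts) on 1 side of all PBS libraries in endothelial cells and on the opposite side in microglia. Acvrl1, a BMP receptor gene of endothelium, differed by -0.38 log2 units with WT exosomes in endothelial cells and by 0.38 in microglia. Tnfaip3, which restrains NF-kB signalling, differed by -0.37 in endothelial cells and 0.82 in microglia in the same comparison. Rpl7, a ribosomal protein gene, differed by 0.18 and -0.32. The mean of the disease-associated microglia list differed by 0.34 in endothelial cells and -0.17 in microglia, and that of hypoxia and glycolysis by 0.16 and -0.06. Hk1, the first enzyme of glycolysis, differed by 0.17 in endothelial cells and -0.43 in microglia with knockout exosomes against PBS.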

How the results depend on the processing

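Alternatives that left out the C libraries, or used log2 of the recovered counts, were added after the data were seen. Setting equal medians, dropping the variance trend or using robust variance left all 63 endothelial and 52 microglia gene results with their direction and side of the threshold. Leaving out each library in turn did so for 617 of the endothelial gene results, while 7 gained and 4 lost a call and 2 reversed, and for 553 in microglia, where 19 reversed. Read depth of the microglia is unknown, so its effect was not assessed. The filter above the endothelial table's high floor left 1068 of 14164 genes for the main test, and with this spread between libraries a microglia difference of 0.5 for WT minus PBS was recovered in 1.2% of simulated genes. Where leaving out a library left 1 in a group, that library was assumed to vary like the other groups. For each value below the cause was not tested, except where fewer genes or libraries entered.

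Without the filter, limma passed 15 endothelial genes in the F test, 9 for WT minus PBS (2 higher, 7 lower), 6 for knockout minus WT (1 higher, 5 lower), 1 for KO1 minus WT, 3 for KO2 minus WT, 17 for knockout minus PBS (all lower) and 3 for KO1 minus KO2, with 27 list calls against 12 and 1 gene shared with the authors' list. Of the 12 main list calls 8 were kept and 4 lost there, and in microglia 5 of 6 were kept. In microglia it passed 1 gene each in the F test, WT minus PBS, KO1 minus WT, knockout minus PBS and KO1 minus KO2, with 1 shared. Without the filter and without the C libraries, KO2 minus WT passed 128 endothelial genes and KO1 minus KO2 125, both on a single KO2 library, with 20 list calls (4 of the 12 lost) and Ptgs2 for knockout minus WT at 0.015. The endothelial F test, WT minus PBS, knockout minus WT and knockout minus PBS passed 0 there with limma (1129, 1088, 1144 and 992 at an unadjusted p under 0.05). Microglia there passed 1 gene for knockout minus PBS and had 14 list calls against 6.

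With the C libraries left out, endothelial counts were 1 for the F test and WT minus PBS, 4 for knockout minus PBS and 0 for KO1 minus KO2 (21 at an unadjusted p under 0.05 with limma, as for the counts in brackets after each 0 that follows), with Ptgs2 for knockout minus WT at 0.015 and 1 gene shared with the authors' list. Microglia counts were 4 for the F test, 8 for WT minus PBS and 3 for knockout minus PBS, with 15 list calls and 4 genes shared.

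On log2 of recovered counts plus 1, endothelial counts were 3 (F test), 9 (WT minus PBS), 21 (knockout minus WT), 14 (KO1 minus WT) and 7 (KO2 minus WT), with 26 list calls (3 of the 12 lost) and 3 genes shared. With plus 10 these were 2, 3, 8, 3 and 2, with 27 list calls (2 lost), 2 shared and 0 (621) for KO1 minus KO2. With plus 50 they were each 2, with 28 list calls (3 lost), 2 shared and 0 (651) for KO1 minus KO2. In microglia, knockout minus PBS passed 2 genes with plus 1 and 3 with plus 50, where WT minus PBS passed 1. Itgam there reversed for WT minus PBS to -0.19, -0.185 and -0.164 and for knockout minus WT to 0.067, 0.064 and 0.052 with plus 1, 10 and 50.

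With only the groups compared, WT minus PBS passed 14 endothelial genes and KO1 minus KO2 0 (24). The stricter filter gave 1 for knockout minus PBS and 0 of 28 genes (0) for KO1 minus KO2 in endothelial cells, and 0 list calls in microglia. Only 1 of the 6 main microglia list calls kept enough members to be tested there. Quantile normalisation gave 1 and library weights 80 for knockout minus PBS in endothelial cells. An estimated correlation or fry left 0 list calls in both cell types. The correlation of WT and knockout differences from PBS, 0.864 and 0.804 in endothelial cells and microglia, was 0.94 and 0.904 over the genes of the stricter filter, 0.801 and 0.744 with KO2 alone and 0.745 in microglia with KO1 alone.

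The letters did not meet the rule for pairing, since 11 of 12 same-letter pairs of endothelial libraries (0.092 to 0.569) and 11 of 15 in microglia (0.02 to 0.554) had a correlation of deviations over 0.1. Different letters gave -0.569 to 0.366 and -0.436 to 0.129. Deviations from the group mean mirror each other in a group of 2 libraries, so these negative values partly follow by construction. They and the counts in the next sentence are not separate evidence. The library of another group that correlated best had the same letter for 9 of 10 endothelial and 10 of 11 microglia libraries, a hint from the data and not from the design. With the letter as a replicate block, endothelial counts were 6 (F test), 14 (WT minus PBS, 7 higher and 7 lower), 1 (KO2 minus WT) and 25 (knockout minus PBS, 15 higher and 10 lower), with 2 of the 12 list calls lost and 6 genes shared. Microglia counts under the block were 25, 46 (WT minus PBS) and 38 (knockout minus PBS), with 18 list calls, 23 genes shared and a correlation of 0.869. With the block and the C libraries left out, endothelial counts were 1, 24 and 12 in the order F test, WT minus PBS and knockout minus PBS, 0 (40) for KO1 minus KO2 and 1 gene shared, and B2m and Ptgs2 for knockout minus WT reversed to 0.021 and 0.028. Microglia counts there were 11, 25 and 19, with 16 list calls and 10 genes shared. With the block and no filter, every endothelial count was 0: the F test (1005), WT minus PBS (1194), knockout minus WT (983), KO1 minus WT (883), KO2 minus WT (992), knockout minus PBS (1018) and KO1 minus KO2 (748). Endothelial lists made 23 calls there, while microglia counts were 11, 19 and 11, with 16 list calls and 10 genes shared. With the block, no filter and no C libraries, every endothelial count was again 0 (674 to 1048, and 753 for KO1 minus KO2) with 22 list calls, B2m at 0.021 and Ptgs2 at 0.028, and microglia counts were 1, 4 and 2, with 16 list calls and 1 gene shared.

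Over the libraries left out in turn, endothelial counts ran from 0 to 2 (F test, 2 without KO1 C), 0 to 14 (WT minus PBS), 0 to 3 (knockout minus WT), 0 to 2 (KO1 minus WT), 0 to 7 (knockout minus PBS) and 0 to 1 (KO1 minus KO2), and genes shared with the authors' list from 0 to 2. Il6 for WT minus PBS ran from -0.304 to 0.882, Tap2 for knockout minus WT from -0.452 to 0.03, and the shared correlation from 0.722 to 0.899. In microglia, knockout minus PBS ran from 0 to 2, list calls from 3 (without PBS B or KO2 A) to 17 (without WT C) and the correlation from 0.709 to 0.889. For knockout minus WT, Acod1 ran from -1.632 to 0.17, Ccl5 from -1.911 to 0.451, Ifit1 from -0.722 to 0.493, Ccl2 from -0.69 to 0.112, Ptgs2 from -1.533 to 0.109 and Itgam from -0.326 to 0.194. Itgam for WT minus PBS ran from -0.189 to 0.331.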

Other observations

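Apart from the unfiltered limma calls, the tests given here were chosen only after the results were seen, and so were the genes named. Without the filter, genes detected in some groups and listed at 0 in others came to the fore in endothelial cells. Arhgdig stood at 275 and 211 normalised counts in the WT libraries and was listed at 0 in all others (0.22 log2 units against PBS, SE 0.018, limma adjusted p = 0.00868). Tns3, which encodes a tensin of cell adhesions, stood at 340 and 141 in the WT libraries and was listed at 0 in all others (0.22, adjusted p = 0.0391). Ptgs1, the constitutive cyclooxygenase, stood at 687 and 705 with WT, 104 in PBS B and 4.33 in KO1 B, and was listed at 0 elsewhere (knockout minus WT -0.38, adjusted p = 0.0409). Other genes were detected with PBS and listed at 0 in all exosome libraries: Pot1a, a telomere protein (339, 311 and 503 with PBS, -0.28, adjusted p = 0.0391), and Chek1, a DNA damage checkpoint kinase (87.1, 142 and 113, -0.15, adjusted p = 0.0391). Map4k2 was listed at 0 in both WT libraries and stood at 1137 or more in every other (-0.71 against PBS, adjusted p = 0.0391). Beside them stands the number of genes above the floor, 11305 to 11952 in the PBS libraries and 9235 to 10739 in the exosome libraries other than KO1 B (11531). With the letter as a block and no filter, none of these genes passed. The calls ended with the C libraries left out, where WT minus PBS and knockout minus WT passed 0 genes (1088 and 1144 at an unadjusted p under 0.05).

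In microglia 2 such genes are named here, from the calls for WT minus PBS and for KO1 minus WT without the filter, which is not a count of all such genes. Pip4k2c, a phosphoinositide kinase gene, stood at 1448 and 1880 with PBS and was listed at 0 in every exosome library except KO2 C (126), with a log2 difference of -1.43 for WT minus PBS (SE 0.167, limma adjusted p = 0.0392). Atp10a, which encodes a phospholipid flippase, stood at 404, 633 and 269 with KO1 and was listed at 0 in all others (0.84 for KO1 minus WT, SE 0.092, adjusted p = 0.021). With the C libraries left out both contrasts passed 0 (788 and 566 at an unadjusted p under 0.05). Within letters, Ptgs2 in microglia was 2.76 and 5.19 times its PBS level in WT A and WT B, and Tnf 3.72 and 2.80 times. The ratio of KO1 to WT for Ptgs2 was 0.774, 0.546 and 0.93 in letters A, B and C, and that of KO2 to WT 0.698, 0.407 and 0.891. For Tnf the ratios were 0.67, 0.611 and 0.968 with KO1, and 0.717, 0.542 and 1.06 with KO2.

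Whether knockout exosomes give a smaller microglial response was tested on list means by exact two-sided permutations within letters, in a family of 8 tests that also asked whether exosomes raise lists in endothelial cells. WT minus knockout was 0.177 for chemokines (exact p = 0.185, adjusted 0.356), 0.204 for cytokines (exact p = 0.222, adjusted 0.356), 0.115 for NF-kB targets (exact p = 0.111, adjusted 0.296) and 0.109 for interferon (exact p = 0.593, adjusted 0.79), where 0.037 was the smallest p possible. In endothelial cells PBS minus exosomes was -0.594 for interferon and -0.295 for cytokines, each lower with PBS in letters A, B and C (exact p = 0.028, the smallest possible, adjusted 0.111), and near 0 for chemokines (exact p = 0.944) and NF-kB targets (exact p = 0.833). None passed the adjustment, so neither hypothesis was decided. With these smallest possible p-values, no test could pass unless most of the 8 reached their smallest p, so the failure itself decides nothing.

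Exosome microglia lettered C lay below those lettered A and B in 58 of 60 inflammatory and interferon genes, by a median of -0.86 on the deposited log2 scale. The lowest median of 10000 lists matched on level was -0.12, and the median of all tested genes was -0.0035. This argues against a fall shared by all genes of that level. The lists were drawn gene by gene from all tested genes, these 60 included, and the pattern was seen in these same genes. Lower depth or complexity as such stays open, because the read depth of the microglia is unknown. Fewer microglia among the sorted cells stays open: 8 microglia markers had a median log2 ratio of counts of -0.83, against -1.58 for the response genes, but 7 of them lay above that response median (Ctss -0.85, C1qb -0.94), and the scale of that test was changed after a first look, from the deposited values (-0.39 against -0.86). A baseline shared by everything lettered C also stays open, as no PBS C microglia library was analysed here and in endothelial cells, over 24 genes, PBS C differed from PBS A and B by a median of -0.05 while exosome C differed from exosome A and B by -0.444. A weaker response to the exosomes of letter C, the biological explanation, was not tested, because the labels do not say what the letters stand for.

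Choroid plexus transcripts set the exosome endothelial libraries lettered A or B apart: 5 of 8 fixed markers (Rarres2, Ttr, Folr1, Kl and Clic6) were higher in each of those 5 libraries than in all 3 PBS libraries. The libraries were set apart by the sums of these same markers, so that count decides nothing. Ttr reached 164800 to 276900 normalised counts there, 0.62 to 1.08% of the total, against 4307 or less with PBS, and Enpp2 32229 to 75378 against 2657 or less, while at most 2 of the 8 markers reached 100 in a PBS library. Choroid plexus cells or their RNA among the sorted cells stay open, and a CD31-positive gate would be expected to remove the epithelium. Plvap, of fenestrated vessels such as those of the choroid plexus, stood at 2383 to 8944 against 1473 or less. Free RNA reaching both sorted cell types stays open too, since Ttr in microglia was at most 9930, in KO2 B, and the labels do not say whether libraries of a letter share slices. An effect of the exosomes on these genes in endothelial cells was not tested.

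The authors' deposited tables list 362 and 238 genes where the limma F test without the letters passed 0 in both cell types, with 119 and 154 genes at an unadjusted p under 0.05. In microglia, with the letter as a term, 181 of the 181 listed genes tested had an unadjusted F test p under 0.05, against 70 without it, which is consistent with a letter term in the authors' model. In endothelial cells the count was 82 of 90, against 70 without the letter, and that explanation stays open there. Genes missed in every library of 1 group are argued against as the whole cause, since 109 of 362 endothelial genes (98 in a group of 2 libraries) and 37 of 238 microglia genes (25) were of that kind, although matched lists held at most 43 and 13. No biological explanation was tested.

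Other splits of the same libraries were also counted. The real splits for knockout minus PBS in endothelial cells and knockout minus WT in microglia passed 0 genes with limma, which all 56 and 84 splits reach by construction, so those counts decide nothing. The highest others were 46 and 126, and the 126 set the 3 C libraries against the other 6, which points to a structure of the samples. By genes at an unadjusted p under 0.05, in fits that took each side as 1 group, the real split had 150 in endothelial cells, reached by 3 of 56 splits (highest other 222), and 145 in microglia, reached by 68 of 84 (highest other 713), so chance cannot be excluded in either. For KO1 minus WT, KO2 minus WT and KO1 minus KO2 in microglia, 10 splits are too few for a share under 0.05, with a real value of 0 (118 to 145 genes at an unadjusted p under 0.05 with limma) and highest others of 1, 0 and 0.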
